A study of Sus scrofa with 9 samples.

How the data were processed

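Small RNA from porcine alveolar macrophages was measured in 9 libraries, 3 untreated, 3 mock-inoculated and sampled at 24 h and 3 inoculated with PRRSV and sampled at 24 h, as the labels give them. Per the labels' protocols, RNA was extracted with TRIzol and sequenced at a commercial provider on an Illumina sequencer. The deposited files hold, for each library, every distinct sequence tag with its length and its raw read count, not normalized, 1 line per tag. The tags span 18 to 45 bases. The adapter trimming, the filters, the aligner and the genome build are not given in the sources used here. Per the series' design text, the submitters tested miRNAs with more than 20 reads. The files name no miRNA, no genome came with them, and no coordinates are given for that reason.

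miRNA names were assigned from the tags. A table of 319 mature sequences was written from general knowledge of conserved mammalian miRNAs and adjusted to the tag forms seen in these files, so the sequence is the identity and the name is a label. The adjustment took place after the tags were seen and before any comparison. Of the 319 names, 255 have a gene in the RefSeq table of the pig assembly Sscrofa11.1, and 214 of the 262 tested. A tag of 18 to 26 bases counted for a mature sequence when it shared its start within 2 bases and its end within 4 bases without mismatch over the mature sequence. Extensions at the 5′ end could not be read without a hairpin. Closely related members such as let-7a and let-7f, miR-23a and miR-23b or miR-27a and miR-27b share end variants and are uncertain. Fragments of tRNA were found with 35 tRNA sequences in 31 groups and fragments of rRNA with 3 sequences (5S, 5.8S and 18S), by an exact match of the whole tag. Viral reads were found with 713 bases in 3 regions of the PRRSV genome, by an exact match of 18 bases anywhere in the tag. These sequences are also from general knowledge, so the viral counts cover part of the virus and serve only to compare libraries. The same viral sequence read backwards matched 0 reads in all libraries. Reads assigned to none of these, including 28S rRNA, other small RNA and pieces of mRNA, were not analysed further here.

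Counting, statistics of shares and figures used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9, and tests across miRNAs used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The grouping, the tests, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. miRNAs with more than 20 counts in at least 3 libraries entered, which left 262. edgeR's robust quasi-likelihood test was fitted to all 9 libraries with TMM factors and group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are RPM, reads scaled to 1000000 miRNA reads after TMM, and for viral reads and fragments to 1000000 reads in all. The alternatives were stricter and looser tag assignment, with a match of 18 bases of the mature sequence anywhere in a tag standing in for the hairpin. Others were DESeq2 size factors, total miRNA count and upper quartile scaling, 3 other filters, DESeq2, limma-voom and limma-trend, fits of only the compared groups, the replicate number as a block, stricter thresholds, and leaving out each library in turn. The rule named up to 10 called miRNAs in each direction, the 10 most abundant, and up to 4 uncalled members of the inflammation and PRRSV lists. Since 0 were called, all others named were chosen after their values were seen and are marked so.

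The 22 fixed lists covered miRNAs induced by inflammation, those reported to restrict or to favour PRRSV, myeloid and stress miRNAs, families and clusters, and markers of 6 other kinds of cell or tissue. The families and clusters were let-7 and miR-98, miR-17-92 with its 2 relatives, miR-23-27-24, miR-30, miR-29, miR-181, miR-15, miR-16 and miR-497, miR-221 and miR-222, miR-99/let-7/miR-125, miR-183, miR-96 and miR-182 and DLK1-DIO3. The markers were for epithelium, red blood cells, lymphocytes, endothelium, fibroblasts and smooth muscle, and striated muscle, liver and nerve. The lists overlap. The 20 with at least 3 measured miRNAs were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists within a comparison. Members adjusted over their list alone were not adjusted over the lists or comparisons. Shares and viral reads were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 against 3. Arm ratios were tested with limma on the log2 ratio of both arms' counts plus 0.5. Counts of tRNA and rRNA fragments by end were added after the data had been seen, tested with edgeR on 102 features scaled by total reads. A fragment is a 5′ one when it starts at the first base of the sequence used and a 3′ one when it ends at the last base. All others are inner, so an end fragment that lacks the outermost base or more counts as inner.

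The replicate numbers are shared between groups. Deviations of same-numbered mock and PRRSV libraries from their group means correlated at 0.394, 0.298 and 0.676, each above the limit of 0.1 set for pairing, so these libraries were treated as possibly paired and the blocked count is given beside the result. PRRSV replicate 2 correlated more with mock replicate 1, at 0.379, than with mock replicate 2, so the pairing is uncertain. It comes from the replicate numbers in the sample titles and the same-number correlations, and whether a number stands for a pig is not stated. No pair of libraries within a group was a duplicate, with chi-square values per degree of freedom from 1226 to 11682. The fit was tested on simulated data for PRRSV against mock with 262 miRNAs. In 20 simulations with 40 changed miRNAs each, 17.5% of 2-fold and 71.5% of 4-fold changes were recovered, 3.00% of calls were false and 0 had the wrong sign. For the 102 fragment features, with 20 raised 4-fold in each of 20 simulations, 56.0% were recovered and 3.45% of calls were false.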

Results

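Small RNA was sequenced from porcine alveolar macrophages, the phagocytes that line the lung airspaces and the main lung target of porcine reproductive and respiratory syndrome virus (PRRSV), an arterivirus. Per the labels, the primary cells came from 3 Landrace pigs aged 5 weeks and raised free of specific pathogens. The 9 libraries formed 3 groups of 3. They were untreated cells, cells mock-inoculated and sampled at 24 h, and cells inoculated with PRRSV at a multiplicity of infection of 5 and sampled at 24 h. Which pig gave which library is not stated, so p-values measure the spread between these libraries, part of which may be technical. The libraries held 37349096 to 53360080 reads each, as counts of distinct sequence tags of 18 to 45 bases. Reads assigned to microRNAs (miRNAs) numbered 32318060 to 39116008 in the untreated, 34883988 to 38443770 in the mock-inoculated and 10434409 to 19311534 in the PRRSV libraries. miRNA levels are given in RPM, reads scaled to 1000000 miRNA reads after TMM normalization, and viral reads in RPM of all reads. At this depth counting error is small beside the spread between libraries for all but the rarest miRNAs.

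The makeup of the small RNA differed between the inoculated cells and both controls. miRNAs made up 33.8% ± 5.11 (SD, n = 3) of reads in the PRRSV libraries, against 71.7% ± 2.98 (n = 3) in the mock and 72.5% ± 2.11 (n = 3) in the untreated libraries. Fragments of transfer RNAs, the adaptors of protein synthesis, made up 16.3% ± 5.72 of reads in the PRRSV libraries, 1.30% ± 0.328 in the mock and 1.40% ± 0.255 in the untreated libraries. Fragments of ribosomal RNA (5S, 5.8S and 18S) made up 9.20% ± 0.998, 4.03% ± 1.19 and 3.03% ± 0.625 in the same order. Reads that matched none of these made up 40.6% ± 1.25, 22.8% ± 2.03 and 22.8% ± 1.44. Tags of 21 to 23 bases, the length of most miRNAs, held 46.0% ± 6.80 of the PRRSV reads and 74.3% ± 1.80 of the mock reads, and tags of 28 to 31 bases held 19.1% ± 9.84 and 2.12% ± 0.824. In each of these 6 measures every PRRSV library lay outside the range of all 6 control libraries. The two-sided exact permutation test gave p = 0.1 for PRRSV against mock and against untreated in each, the smallest p that 3 libraries against 3 allow. Between mock and untreated the exact permutation p lay between 0.4 and 1 for these measures. The 6 measures are not independent, since a smaller miRNA share by itself raises the share of every other class. The PRRSV to mock ratio of mean shares was 12.5 for tRNA, 2.28 for rRNA and 1.78 for reads that matched none. Whether rRNA and unmatched reads rose beyond the effect of fewer miRNA reads was not tested.

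**Figure D1:**
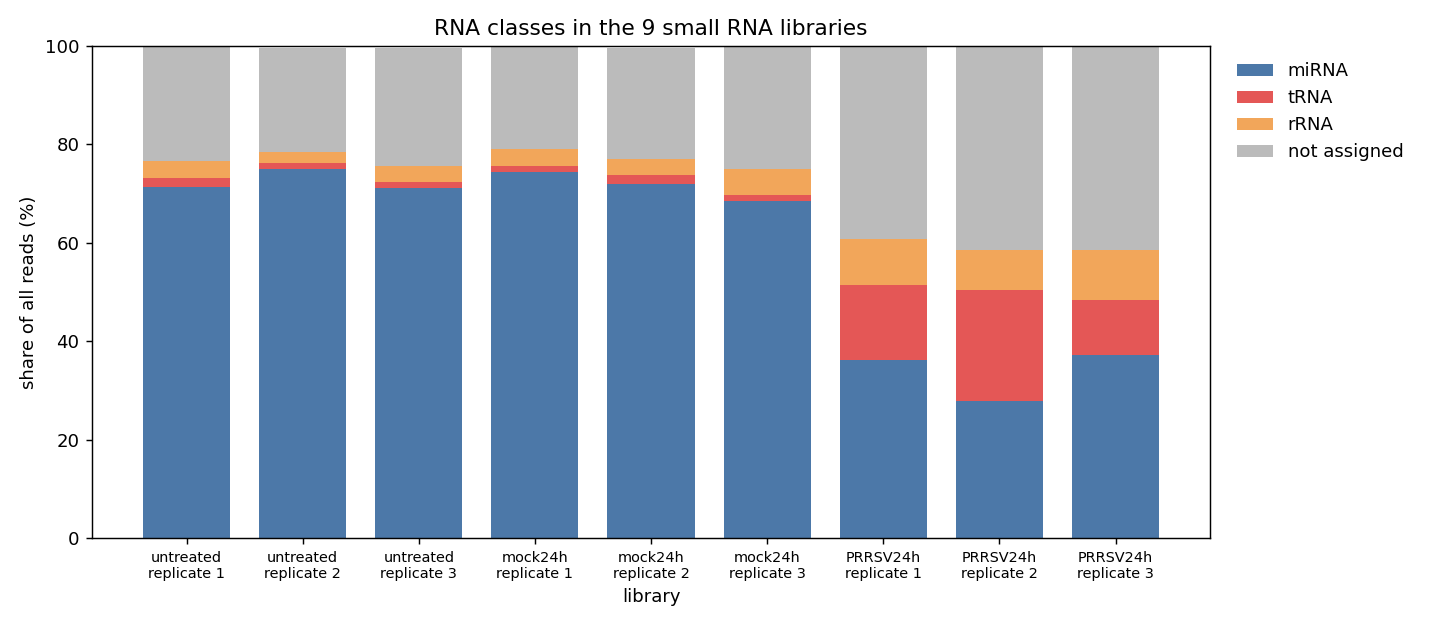
Share of all reads (vertical axis, percent) assigned to miRNAs, tRNAs, rRNAs or to none of them in each of the 9 libraries (horizontal axis; one stacked bar per library). miRNAs took 27.9% to 37.3% of reads in the 3 PRRSV libraries and 68.5% to 74.9% in the 6 control libraries.

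A few miRNAs held most of the miRNA reads in every group. miR-21-5p (TAGCTTATCAGACTGATGTTGA), which is abundant in activated macrophages, held 35.1% of miRNA counts over all 9 libraries. miR-27a-3p (TTCACAGTGGCTAAGTTCCGC) held 9.31%, miR-34a-5p (TGGCAGTGTCTTAGCTGGTTGT), a p53-responsive miRNA, 6.91%, miR-191-5p (CAACGGAATCCCAAAAGCAGCT) 5.88% and miR-23a-3p (ATCACATTGCCAGGGATTTCC) 5.55%. let-7i-5p (TGAGGTAGTAGTTTGTGCTGTT) held 3.50%, miR-378a-3p (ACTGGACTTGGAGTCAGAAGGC) 3.32% and miR-24-3p (TGGCTCAGTTCAGCAGGAACAG) 3.17%. let-7a-5p (TGAGGTAGTAGGTTGTATAGTT) held 2.24% and let-7g-5p (TGAGGTAGTAGTTTGTACAGTT) 2.20%, and the 10 together held 77.2%. The share of miRNA reads from miR-21-5p was 35.2% ± 4.19 (n = 3) in the PRRSV, 35.1% ± 7.24 (n = 3) in the mock and 35.1% ± 6.62 (n = 3) in the untreated libraries, and differed by less than the spread between libraries. The let-7 members, and the pairs miR-23a/miR-23b and miR-27a/miR-27b, differ by 1 or a few bases, so their split is uncertain.

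The comparison of PRRSV-inoculated with mock-inoculated cells at 24 h asked which miRNAs change with infection. miR-155-5p (TTAATGCTAATTGTGATAGGGG), a miRNA induced by inflammatory signals in macrophages, stood at 8550.3 ± 3761 RPM (SD, n = 3) in the PRRSV libraries and 2982 ± 494 in the mock libraries, a log2 difference of 1.52 (SE 0.36; edgeR adjusted p = 0.409). miR-221-3p (AGCTACATTGTCTGCTGGGTTTC) stood at 999.7 ± 173 against 559 ± 78.4, a log2 difference of 0.84 (SE 0.24; edgeR adjusted p = 0.665), and its other arm miR-221-5p had a log2 difference of 1.21 (SE 0.43). miR-93-3p, a minor arm near 23.4 RPM in the PRRSV libraries, had a log2 difference of 1.03 (SE 0.32), and miR-193a-5p one of -0.66 (SE 0.25). These 5 were picked after their values were seen, and in each the PRRSV libraries did not overlap the mock libraries. Of the most abundant miRNAs, miR-24-3p was the furthest from 0, with a log2 difference of -1.13 (SE 0.53) on mock values of 48653 ± 39336 RPM, followed by miR-378a-3p at -0.68 (SE 0.35). Mock replicate 3 carried most of the former, and without it miR-24-3p was at -0.27 and miR-378a-3p at -0.36. The other 8 of the 10 most abundant lay between -0.16 (miR-191-5p) and 0.20 (miR-27a-3p).

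By edgeR's quasi-likelihood test, 0 of 262 miRNAs passed the threshold of 0.05 on the adjusted p in PRRSV against mock cells. At an unadjusted p under 0.05 there were 9, of which 6 were higher and 3 lower in the PRRSV libraries. They were 3.44% of the miRNAs, where a share of 0.05 passes by chance. The count was 4 without PRRSV replicate 1, 20 without mock replicate 2 and 14 with the replicate number as a block. DESeq2 called 1 miRNA, miR-155-5p, with an adjusted p of 0.0486, and limma-voom and limma-trend called 0. With the replicate number as a block over all groups, untreated included, edgeR called 1, again miR-155-5p, with a log2 difference of 1.44 and an adjusted p of 0.0282. With the block in a fit of only the PRRSV and mock libraries, edgeR called 0, with a lowest adjusted p of 0.203. Over 15 alternatives of scaling, tool, fitted groups, block and libraries the adjusted p of miR-155-5p ranged from 0.0282 to 0.962. The groups did not overlap for 22 miRNAs, or 8.40%, where chance gives 10% if the libraries are not paired.

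**Figure D2:**
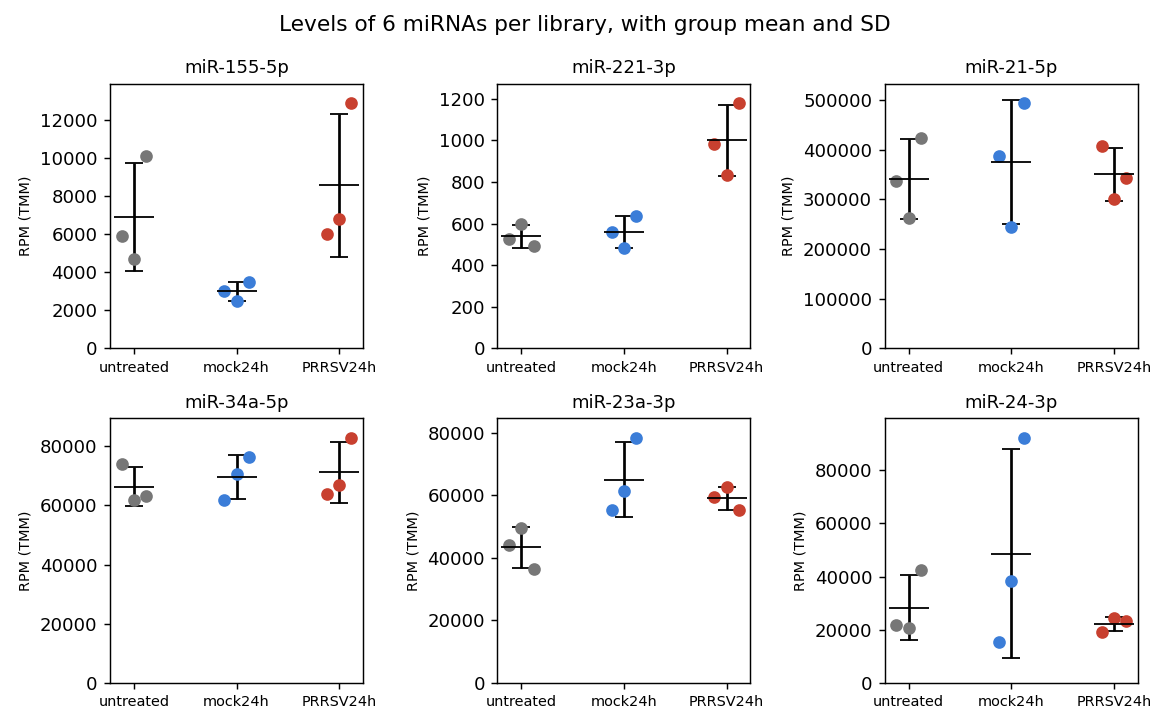
RPM of miRNA reads after TMM scaling (vertical axes, starting at 0) of 6 miRNAs in the untreated, mock-inoculated and PRRSV-inoculated libraries (horizontal axes). Points are libraries and bars are group means with SD (n = 3), and miR-155-5p averaged 8550.3 in the PRRSV, 2982 in the mock and 6877 in the untreated libraries.

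The list of miRNAs induced by NF-kB and Toll-like receptor signals held 27 measured miRNAs from 18 named members, counting each arm. Of these, 12 were higher and 15 lower in PRRSV than in mock cells. Past the threshold were 0 over all miRNAs and 1, miR-155-5p, adjusted over the list alone. The median log2 difference of that list was -0.07, while camera placed it on the higher side with an adjusted p of 0.790. Its most abundant members were miR-21-5p (log2 difference -0.10, SE 0.26), miR-34a-5p (0.03, SE 0.17), miR-146b-5p (0.23, SE 0.26; TGAGAACTGAATTCCATAGGCT) and miR-223-3p (-0.06, SE 0.20; TGTCAGTTTGTCAAATACCCCA), the last of them a myeloid miRNA. The list of miRNAs reported in earlier work to restrict PRRSV held 25 measured miRNAs from 19 named members, since a name without an arm covered every measured arm. Of these 25, 15 were higher and 10 lower (camera adjusted p = 0.657). Among them, miR-378a-3p, given above, had a log2 difference of -0.68, and of -0.36 without mock replicate 3. miR-23a-3p had a log2 difference of -0.14 (SE 0.18), miR-26a-5p (TTCAAGTAATCCAGGATAGGCT) -0.02 (SE 0.18) and let-7f-5p (TGAGGTAGTAGATTGTATAGTT) 0.02 (SE 0.26). Of 5 reported to favour PRRSV, 4 were higher and 1, miR-24-3p, was lower (camera adjusted p = 0.790). miR-22-3p (AAGCTGCCAGTTGAAGAACTGT) had a log2 difference of 0.15 (SE 0.18), miR-29a-3p (TAGCACCATCTGAAATCGGTTA) 0.25 (SE 0.36) and miR-140-5p (CAGTGGTTTTACCCTATGGTAG) 0.07 (SE 0.24).

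One family was called as a set in PRRSV against mock cells. The list held both arms of miR-221 and miR-222, of which the 3p arms are known to target the cell cycle inhibitor p27. These 4 miRNAs had a median log2 difference of 0.68, and camera gave an adjusted p of 0.0400 with its preset correlation. That call was lost with an estimated correlation (adjusted p = 0.674 with an estimated correlation), and fry gave an adjusted p of 0.681. With 1 library left out it passed in 2 of 6 fits. Of the 4, 3 were higher and 1, miR-222-5p, was lower, and 2 passed when adjusted over the list alone. For the remaining lists the camera adjusted p stands in parentheses. The miR-29 family was higher in 4 of 4 members (0.386), the miR-30 family in 6 of 8 (0.657), the miR-181 family in 4 of 6 (0.463) and the miR-15, miR-16 and miR-497 family in 6 of 9 (0.657). The let-7 and miR-98 family was lower in 8 of 10 (0.578), the miR-23-27-24 clusters in 6 of 8 (0.578) and the miR-99/let-7/miR-125 clusters in 8 of 10 (0.623). The 3 clusters related to miR-17-92 were higher in 12 of 20 (0.657), with a median log2 difference of 0.08 but a mean of -0.01, and the miR-183, miR-96 and miR-182 cluster in 2 of 3 (0.786). The p53 and stress list was higher in 3 of 5 (0.692), the myeloid list in 5 of 9 (0.463), and the imprinted DLK1-DIO3 cluster was lower in 6 of 7 (0.657). Mock replicate 1 carried that last direction, and without it the 6 DLK1-DIO3 miRNAs still tested were all higher in the PRRSV libraries, with a median log2 difference of 1.36. Markers of other cell types gave no call either. Epithelial markers were higher in 8 of 13 (0.790), lymphocyte markers in 5 of 9 (0.657), muscle, liver and nerve markers in 3 of 5 (0.786), and fibroblast and smooth muscle markers lower in 5 of 6 (0.657). Red cell and endothelial markers had 2 measured miRNAs each, too few for the set test, with 1 higher and 1 lower in both. Camera placed 6 lists on the higher side although their mean log2 difference was below 0, namely the inflammation list (-0.07), the clusters related to miR-17-92, those reported to restrict (-0.01) or favour (-0.13) PRRSV and the lymphocyte (-0.01) and muscle, liver and nerve (-0.03) markers.

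Neither group in the comparison of mock-inoculated with untreated cells was inoculated with PRRSV per the labels, but 1 untreated library held many viral reads, as given below. The labels give no time for the untreated cells, so whether they were cultured for 24 h is not known. miR-155-5p stood at 2982 ± 494 RPM (SD, n = 3) in the mock libraries and 6877 ± 2833 in the untreated libraries, a log2 difference of -1.21 (SE 0.35; edgeR adjusted p = 0.688). miR-23b-3p (ATCACATTGCCAGGGATTACC) had a log2 difference of 0.75 (SE 0.23), and both were picked after their values were seen. miR-23a-3p had a log2 difference of 0.58 (SE 0.19), and the mock libraries held 64954 ± 12017 RPM of it against 43415 ± 6567. miR-24-3p (0.78, SE 0.53) and miR-378a-3p (0.60, SE 0.34) followed among the 10 most abundant, but without mock replicate 3 they were at -0.07 and 0.28. The other 7 lay between -0.21 (let-7i-5p) and 0.14 (miR-21-5p). miR-223-3p had a log2 difference of 0.39 (SE 0.20). edgeR called 0 of 262 miRNAs, with 16, or 6.11%, at an unadjusted p under 0.05 (7 higher, 9 lower) and a lowest adjusted p of 0.688. DESeq2, limma-voom and limma-trend called 0, and the groups did not overlap for 28 miRNAs, or 10.7%, where chance gives 10%.

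As sets, 2 families were called between mock and untreated cells. The miR-30 family was higher in the mock libraries in 8 of 8 members, with a median log2 difference of 0.44, and camera gave an adjusted p of 0.0124 (adjusted p = 0.806 with an estimated correlation). With 1 library left out that median ranged from 0.125 to 0.640. The miR-183, miR-96 and miR-182 cluster, first described in sensory organs and also expressed in epithelium and lymphocytes, was higher in 3 of 3, with a median of 0.90 and an adjusted p of 0.0179 (adjusted p = 0.806 with an estimated correlation). fry gave an adjusted p of 0.662 for both, and with 1 library left out each passed in 5 of 6 fits but not without mock replicate 2. None of these members passed alone, whether over all miRNAs or adjusted over the list alone. The miR-23-27-24 clusters were higher in 7 of 8 (camera adjusted p = 0.0531) and 2 of them passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.806, and with 1 library left out it ranged from 0.0186 to 0.336 and passed in 2 of 6 fits. The miR-99/let-7/miR-125 clusters were higher in 10 of 10, also with a camera adjusted p of 0.0531 (adjusted p = 0.806 with an estimated correlation). With 1 library left out that p ranged from 0.0101 to 0.448 and passed in 2 of 6 fits, and without mock replicate 1 it was 0.448, with 9 of 10 higher. The wider epithelial marker list, which includes the miR-183 cluster, was lower in 10 of 13, with a median of -0.48 (camera adjusted p = 0.335). Upper quartile scaling moved the median of all miRNAs by -0.15, less than the smallest miR-30 difference of 0.29 with all libraries.

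PRRSV-inoculated and untreated cells differ in inoculation and perhaps in time in culture, and the same untreated library is included. miR-212-3p (TAACAGTCTCCAGTCACGGCC), a product of the miR-212/132 cluster, stood at 38.3 ± 8.70 RPM (SD, n = 3) in the PRRSV libraries and 88.7 ± 18.7 in the untreated libraries, a log2 difference of -1.21 (SE 0.30; edgeR adjusted p = 0.224). miR-93-3p (ACTGCTGAGCTAGCACTTCCCG) stood at 23.4 ± 4.53 against 9.66 ± 1.94, a log2 difference of 1.27 (SE 0.32), miR-221-3p differed by 0.90 (SE 0.24) and miR-193a-5p by -0.97 (SE 0.25), each with an edgeR adjusted p of 0.224. These 4 were picked after their values were seen. miR-155-5p had a log2 difference of 0.31 (SE 0.35), which is less than the spread between libraries. Over 15 alternatives that difference ranged from -0.11 to 0.72 and changed sign in 1. Of the 10 most abundant miRNAs, miR-23a-3p had the largest difference at 0.44 (SE 0.19) and the other 9 lay between -0.35 (miR-24-3p) and 0.10 (miR-34a-5p). Without untreated replicate 3 miR-24-3p was at 0.09, and without untreated replicate 2 at -0.59. edgeR called 0 of 262 miRNAs, with 22, or 8.40%, at an unadjusted p under 0.05 (8 higher, 14 lower). DESeq2 called 2, miR-212-3p with an adjusted p of 0.0139 and miR-93-3p with 0.00689, and limma-voom and limma-trend called 0. Over the same 15 kinds of alternative the adjusted p ranged from 0.0139 to 0.744 for miR-212-3p and from 0.00689 to 0.744 for miR-93-3p. The groups did not overlap for 54 miRNAs, or 20.6%, where chance gives 10%.

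The families called between PRRSV and untreated cells were again the miR-30 family and the miR-183 cluster. The miR-30 family was higher in 8 of 8 members with a median log2 difference of 0.49 and a camera adjusted p of 0.00594 (adjusted p = 0.753 with an estimated correlation). The miR-183, miR-96 and miR-182 cluster was higher in 3 of 3 with a median of 0.95 and an adjusted p of 0.0258 (adjusted p = 0.753 with an estimated correlation), and 2 members passed when adjusted over the list alone. With 1 library left out the first passed in 5 and the second in 4 of 6 fits. The wider epithelial marker list, which includes the miR-183 cluster, was lower in 8 of 13, with a median of -0.29 (camera adjusted p = 0.546). The miR-221 and miR-222 family was higher in 3 of 4 (camera adjusted p = 0.130), also with 2 adjusted over the list alone. The list induced by NF-kB and Toll-like receptors had 2 of 27 adjusted over the list alone, a median of 0.10 with a mean of -0.08, and a camera direction on the lower side (adjusted p = 0.841). Both of these comparisons use the same untreated libraries, so their differences share chance values. Across the 262 miRNAs the mock and PRRSV differences from untreated had a correlation of 0.586, where 100 simulations of unchanged groups against these controls gave 0.491. The covariance was 0.196 against a simulated 0.181 (SD 0.0441), a difference of 0.0151, and the 3 controls are too few to split.

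The balance of the arms of a hairpin does not depend on library scaling. Among 64 hairpins with both arms measured, limma called 0 in each of the 3 comparisons. At an unadjusted p under 0.05 there were 5 in PRRSV against mock, 3 in mock against untreated and 4 in PRRSV against untreated cells. The lowest adjusted p values by limma were 0.297, 0.719 and 0.292.

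Reads that match PRRSV sequence were counted in every library as a check of the inoculation. The PRRSV libraries held 11.4, 3.78 and 13.9 viral RPM (replicates 1, 2 and 3; 95% Wilson intervals 10.5 to 12.5, 3.20 to 4.45 and 13.0 to 15.0). The mock libraries held 2.48 (2.09 to 2.95), 0.268 (0.157 to 0.459) and 0.391 (0.253 to 0.604). The libraries labelled untreated replicates 2 and 3 held 0.115 (0.0527 to 0.251) and 0.308 (0.184 to 0.517), and the library labelled untreated replicate 1 held 35.0 (33.4 to 36.6), or 1865 reads, more than any PRRSV library. These intervals cover counting error only. The mean was 9.72 ± 5.30 (SD, n = 3) in the PRRSV and 1.05 ± 1.24 in the mock libraries, with an exact permutation p of 0.1, and 11.8 ± 20.1 in the untreated libraries, with an exact permutation p of 1 against the PRRSV libraries. The PRRSV minus untreated difference was -2.07 RPM, 9.51 without untreated replicate 1 and 0.901 without PRRSV replicate 2. The mock minus untreated difference was -10.7 RPM, and 0.835 without untreated replicate 1. With a match of 22 bases in place of 18 mock replicate 1 held 0.484 RPM in place of 2.48, the PRRSV libraries 5.21, 1.93 and 7.23, and untreated replicate 1 14.6 in place of 35.0, so the level of mock replicate 1 is uncertain. At 22 bases the PRRSV minus mock difference was 4.51 against 8.67 RPM, mock minus untreated -4.62 and PRRSV minus untreated -0.105. The viral label check therefore went against 1 library, and comparisons with the untreated group include it. Without it edgeR called 0 miRNAs in mock and in PRRSV cells against the other 2 untreated libraries, with 7 and 11 at an unadjusted p under 0.05, and 0 in PRRSV against mock cells, with 8 at an unadjusted p under 0.05.

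**Figure D3:**
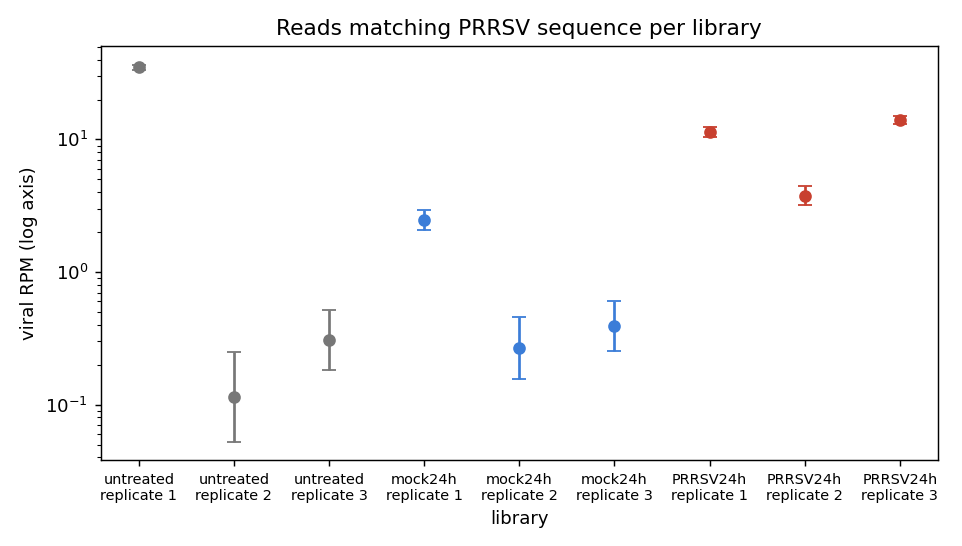
Reads matching PRRSV sequence, in RPM of all reads (vertical axis, logarithmic) in each of the 9 libraries (horizontal axis), with 95% Wilson intervals for counting error. The library labelled untreated replicate 1 lies highest at 35.0, above the PRRSV libraries at 3.78 to 13.9, and the other 5 control libraries lie at 0.115 to 2.48.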

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

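The 5 tests of explanations in this part were chosen after the results they bear on had been seen, while the count of viral reads and the shares of RNA classes were planned.

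Fragments from the 5′ end of tRNAs, a class that the miRNA comparisons leave out, made up 12.3% ± 5.54 (SD, n = 3) of reads in the PRRSV libraries, against 0.453% ± 0.192 in the mock and 0.319% ± 0.170 in the untreated libraries. A smaller share of miRNA reads alone would leave the fragments' part of the remaining reads alike, but that part was 18.3% ± 6.69 against 1.61% ± 0.679, a ratio of 11.4. Breakdown that cuts all RNA alike would lift 5′ tRNA pieces and inner 18S rRNA pieces together, but the median log2 difference of the 31 5′ tRNA features, 4.37, exceeded that of inner 18S rRNA, 1.47, by 2.90 (SE 0.62). A candidate explanation is cleavage of tRNAs near the anticodon during infection, since stress is known to induce it, but no test here decides it. Some 5′ fragments ended earlier, such as those of Met-CAT, where a tag shorter than 28 bases held 93.6%. Lengths of 28 to 31 bases made up 61.2% of 5′ tRNA fragments in PRRSV replicate 1 and 92.4% in replicates 2 and 3. In mock replicate 2 they made up 66.1%. Uneven breakdown of RNA in dying cells also stays open and was not tested.

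Inner tRNA fragments, outside the miRNA comparisons too, made up 3.71% ± 2.24 of reads in the PRRSV libraries, against 0.487% ± 0.0421 in the mock and 0.432% ± 0.116 in the untreated libraries. End fragments that lack the outermost base or more are counted among them, and so are pieces from the middle of a tRNA. The main inner tags of tRNA-Gln-CTG (51.6% of its inner fragments) and tRNA-Gln-TTG (48.9%) were such middle pieces. Those of tRNA-Gly-GCC (14.1%) and tRNA-Val-AAC/CAC (17.3%) were 5′ fragments without their first bases. How the inner share divides between these kinds was not tested.

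The library labelled untreated replicate 1 held 35.0 viral reads per 1000000 reads (RPM), where untreated cells should hold about none. A PRRSV library under this label would bring that group's 5′ tRNA fragments, but their share was 0.510% (95% Wilson interval 0.509 to 0.512, counting error only), below the 8.89% (8.88 to 8.89) of the lowest PRRSV library. Reads carried over from the 3 PRRSV libraries alone would stay below the level of their source, but the level was 2.51 times that of the PRRSV library with most, and with a match of 22 bases it was 14.6 against 7.23 RPM. A strain as distant from the inoculum as the sequence used for matching would differ at many positions, but the majority base differed from PRRSV replicate 3 at 1 of 408 positions, or 0.245%, where that library differed from the matching sequence at 16. Viral RNA or virus that reached these cells or this sample, and carry-over from libraries not analysed here, may be the source and were not tested.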

How the results depend on the processing

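Tests of tRNA and rRNA fragments, the block within only the compared groups and the fit without the library labelled untreated replicate 1 were added after the data had been seen. The count of called miRNAs was 0 in all 3 comparisons under every alternative, leaving out each library included, except 3. DESeq2 called 1 in PRRSV against mock and 2 in PRRSV against untreated cells, and the replicate block called 1 in PRRSV against mock cells. The cause was not tested. With the block in a fit of only the compared groups the count was 0 in each. The numbers do not pair the untreated libraries, whose same-number correlations were 0.0465, 0.101 and 0.402 with mock and -0.0875, 0.486 and 0.433 with PRRSV libraries, and not every library correlated best with its own number. There the block left 0 calls. It brought the camera adjusted p of the miR-99/let-7/miR-125 list between mock and untreated cells from 0.0531 to 0.0307, both at the preset correlation. With an estimated correlation and without the block that camera adjusted p was 0.806. The block changed no other list call. For fragments the block gave 57, 2 and 70 calls in PRRSV against mock, mock against untreated and PRRSV against untreated cells, against 58, 0 and 71. Leaving out 1 library gave 50 to 65, 0 to 7 and 62 to 71; between mock and untreated cells it gave 7 without mock replicate 2, 3 without mock replicate 1 or 3, 1 without untreated replicate 2 or 3, and 0 without untreated replicate 1. Fewer libraries entered those fits, and the cause was not tested otherwise. Scaling by miRNA sizes gave 73 higher and 0 lower against 55 and 3 in PRRSV against mock, and 76 and 1 against 59 and 12 in PRRSV against untreated cells. All 5 list calls were lost with an estimated correlation and with fry. The direction by camera changed in 0, 1, 2 and 4 of 60 list tests under the estimated correlation, fry, the block and total count, all of them uncalled. With 1 library left out, also added later, called lists passed in 21 of 30 fits with 0 changes of direction, and 5 of 55 uncalled lists passed in 8 of 330 fits, with 58 changes of direction. Of 765 alternative values of the miRNAs named by rule, 75 changed sign and 0 passed. Of 360 for those chosen later, 31 changed sign and 4 passed. Upper quartile scaling moved the median of all miRNAs by -0.15 in mock and -0.23 in PRRSV against untreated cells. Depth limits the rarest miRNAs and the viral reads, and equal depth was not tested.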

Other observations

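The tests by fragment in this part were chosen after the tRNA shares had been seen, and the splits of the miRNA counts were made after those counts were known.

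Fragments of most tRNAs were higher in PRRSV than in mock cells. Of 31 tRNA groups, the 5′ fragments of 25 rose and 0 fell, with a median log2 difference of 4.37. The 5′ fragments of tRNA-Val-AAC/CAC were most abundant, at 42634 ± 12894.5 reads per 1000000 reads (RPM; SD, n = 3) in the PRRSV and 820.1 ± 526 in the mock libraries, a log2 difference of 5.70 (SE 0.62; edgeR adjusted p = 3.06e-07). One tag, GTTTCCGTAGTGTAGTGGTTATCACGTTC, held 70.6% of them. tRNA-Gly-GCC (GCATTGGTGGTTCAGTGGTAGAATTCTCG as the main tag) rose from 437 ± 287 to 15306 ± 10786 RPM, with replicate 2 the highest in both groups. The 6 groups whose 5′ fragments did not pass were Leu-AAG (log2 difference 1.43, SE 0.65), Arg-ACG (1.27, SE 0.73), Leu-CAG (0.50, SE 0.65), Asn-GTT (0.22, SE 0.53), Ser-AGA (-0.11, SE 0.60) and Ser-GCT (-0.83, SE 0.71). Inner fragments, which include shortened end fragments, rose in 25 of 31 groups, with a median of 2.58. Those of both glutamine tRNAs had the largest differences, 5.58 (SE 0.68) for Gln-TTG and 5.51 (SE 0.71) for Gln-CTG. These 2 are nearly identical in sequence. Tags that fit both were left out, so the values rest on tags that differ by as little as a base. 3′ fragments rose in 3 groups and fell in 3, with a median of -0.53, but scaling by miRNA sizes gave 10 higher and 0 lower with a median of 0.70. The 3 lower fragments were all 3′ ones, and the count of lower fragments was 0 without mock replicate 2 or PRRSV replicate 1, 1 without PRRSV replicate 2 or with the block, and 11 without mock replicate 3. Of 3 rRNAs, inner fragments of 18S (1.47, SE 0.44) and 5S (1.21, SE 0.52) rose relative to all reads. A smaller share of miRNA reads lifts every other fragment at this scaling. Whether these rRNA fragments rose, or how far 3′ tRNA fragments fell, among the reads that are not miRNA was not tested. All of these were scaled by total reads, and the share of 5′ tRNA fragments of 28 to 31 bases was 82.0% ± 18 in the PRRSV and 45.9% ± 17.8 in the mock libraries (exact permutation p = 0.2).

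Counts of called fragments were 58 of 102 (55 higher, 3 lower) in PRRSV against mock, 0 in mock against untreated and 71 (59 higher, 12 lower) in PRRSV against untreated cells by edgeR, with 64, 11 and 72 at an unadjusted p under 0.05. Against untreated cells the 5′ fragments of 25 of 31 tRNA groups rose, and the 3′ fragments of 12 fell and of 2 rose, among the former tRNA-Gly-GCC (log2 difference -2.39, SE 0.52) and tRNA-Val-AAC/CAC (-2.55, SE 0.78). The count of lower fragments was 7 without PRRSV replicate 3 and 8 without PRRSV replicate 1 or 2. Scaling by miRNA sizes left 1 of those 3′ groups lower and 9 higher. Of the 10 splits of each comparison's 6 libraries into 3 and 3, 1 gave as many calls as the real split in PRRSV against mock, the real one itself, and likewise 1 in PRRSV against untreated, with 0 as the highest of the others in both. In mock against untreated cells the real split and all others gave 0, which says nothing either way. With 10 splits the share cannot fall under 0.05. In the comparisons with PRRSV libraries every other split put PRRSV and control libraries into the same group. That widens the spread within groups, so few calls were likely there beforehand, and the contrast with the real split adds no support.

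For miRNAs the real count was 0 in all 3 comparisons, which every split must reach, so the splits say nothing about those counts. The highest of the other splits was 1 in PRRSV against mock cells and 0 in the remaining comparisons. At an unadjusted p under 0.05 the real split gave 9 in PRRSV against mock, 16 in mock against untreated and 22 in PRRSV against untreated cells. The 3 other splits that part all 3 replicate numbers gave 2 to 11, 9 to 15 and 1 to 6 in the same order. The 6 that part 1 number gave 9 to 38, 9 to 44 and 1 to 21, so the real split gave the most only in PRRSV against untreated cells.

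Some miRNAs varied within a group by more than between groups. miR-24-3p had an SD of 39336 on a mean of 48653 RPM in the mock libraries, with 92143 in replicate 3, where the PRRSV libraries gave 22241 ± 2720. miR-424-5p, picked after its values were seen, stood at 2290.4 ± 1585 in the PRRSV, 2287 ± 1341 in the mock and 2187 ± 1648 in the untreated libraries. PRRSV replicate 2 held the fewest viral reads of its group, 3.78 RPM, and the most 5′ tRNA fragments, 18.7% of reads (95% Wilson interval 18.72 to 18.74), where replicates 1 and 3 held 8.89% (8.88 to 8.89) and 9.41% (9.40 to 9.42). These intervals cover counting error only. With 3 libraries no relation between these values was tested.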
